A study of Mus musculus with 24 samples.

How the data were processed

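Gene expression was measured by bulk RNA sequencing of total RNA from whole lung and whole small intestine of E11.5 mouse embryos, in 24 libraries that form 6 groups of 4: control, Cenpj mutant and Ift88 mutant in each organ. Groups follow the genotypes and organs of the labels. Per the labels, tissue was lysed in Trizol and RNA was purified with an RNeasy Micro kit.

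The values came from a single deposited file of 55536 genes with 24 columns of normalized counts, 1 per library. Per the file headers and the values, the signal in these columns is the read count of each gene divided by 1 size factor per library, rounded by the authors to 1 decimal, and a further deposited signal column is the mean of the 24. The deposited ratio columns are linear fold changes between group means made by the authors for 9 comparisons, 1 of which is a spreadsheet formula result. Per the file headers, the deposited p-value columns are the raw p-value and the FDR of the authors' test, with no FDR for genes the authors left out. The submitters' processing notes name STAR 2.5.2b, DESeq2 1.16.1 and the builds GRCm38 and mm10. The counting tool, the annotation release and the strand setting are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain.

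The design had allowed for counts, in which case edgeR would have been the main test, or for normalized values, in which case limma would be. The columns hold normalized values, so limma was used. Low values were whole multiples of 1 step per library within a tolerance of 0.051 up to 500, so whole reads could be recovered. In 20 libraries the step differed clearly from rounding, and in 4 it lay too near 1 to be told apart from it. Recovered reads were used for depth, for edgeR, DESeq2 and limma-voom, and totalled 96.1 to 120.88 M reads per library (median 108.4), with 21994 to 26529 genes detected. The most common read count of barely detected genes was 12 to 42 (median 19.5), as if each molecule had been read many times, and totals divided by it came to 2.32 to 10.07 M (median 5.77). Counting error may therefore be larger than the totals imply, and it was not separated from the spread between libraries. Replicates correlated at 0.922 to 0.977. Deviations of same-numbered libraries from their group means correlated above 0.1 in all 4 pairs of control lung with control intestine (0.244, 0.101, 0.108 and 0.182), so the numbers were taken to pair these samples. This was found in the data and is not stated in the labels, and in no other pair of groups did all 4 pairs pass.

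The main test was limma-trend on log2(value + 1) for genes with a mean normalized count of 1 or more over the libraries fitted, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Comparisons within an organ were fitted on its 12 libraries, and the differences between organs and the comparison of control lung with control intestine on all 24. Gene lists, 45 in number with 685 of 695 symbols present in the table, were written before the data were examined, and the 44 with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The design named voom values for the lists, and log2(value + 1) was used instead to match the main test. For each list the members past the threshold were counted over all genes tested and with the adjustment over the list alone. Camera with an estimated correlation and fry were run as alternatives.

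Also written before the data were examined were the comparisons, the tests, the alternatives planned and the rule for naming genes. Under this rule the text names Cenpj and Ift88, and in each comparison the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of 1 or more and all 4 libraries of one group above all 4 of the other, without predicted genes that have only a number for a name. Where fewer than 5 qualify, it names the 5 with the smallest p. It also names up to 4 members per list with the smallest p past the threshold, or the 2 with the highest mean where fewer than 2 pass, and any member of the lists of p53, ERK and hedgehog targets, hedgehog ligands and apoptosis genes. A few genes that the rule names are not reported here. For differences between organs only the adjusted p and the mean log2 CPM apply. Chosen after the data were seen were the split of libraries by ribosomal RNA (over 2000 reads per M reads) and Rn7sk (over 500 normalized counts), the lists of the Lin28 and let-7 axis and of globins, which lists the text describes, and the alternatives named as such below.

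Alternatives fixed before the data were seen were edgeR with DESeq2-type factors or library size only, DESeq2, limma-voom, pseudocounts of 0.1 and 0.5, no filter beyond 1 read, a filter of CPM of 1 or more in at least 4 libraries, the replicate number as a block, only the groups of the comparison, all 24 libraries in one fit, a sex covariate, leaving out Xist and Y-linked genes, leaving out 30 erythroid and hepatic genes, leaving out 752 genes within 10 Mb of Cenpj and Ift88, leaving out each library in turn, an adjusted p under 0.01, and an absolute log2 fold change of 1 or more. Alternatives chosen after the data were seen were edgeR with TMM factors on recovered reads, limma after TMM scaling or with equal totals, library kind as a term, and leaving out the male and mixed libraries. Every other split of the libraries into groups of the same sizes was run, or 100 splits drawn with a fixed seed where there were more. Overlap of calls against shared controls was compared with 100 simulations of unchanged groups. The tools were tested on simulated data with 200 changed genes. For the comparison of Cenpj mutant with control lung, 7.28% of limma calls, 4.14% of edgeR calls, 36.2% of DESeq2 calls and 11.3% of limma-voom calls were false, and limma found 54% of 2-fold and 86% of 4-fold changes. Exon length and GC content came from the GENCODE annotation of GRCm38. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.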

Results

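Bulk RNA sequencing measured gene expression in whole lung and whole small intestine of mouse embryos at E11.5, a stage at which, per the labels, no overt defect was yet seen. The 24 libraries formed 6 groups of 4, with 3 genotypes in each organ. In all 3 genotypes Cre recombinase was expressed from the Shh locus, which is active in the epithelium of both organs. Control embryos carried 1 working and 1 conditional allele of Cenpj, so their epithelium kept a single working copy. Cenpj mutants carried 1 null and 1 conditional allele of Cenpj, which encodes a protein needed to build centrioles. Ift88 mutants carried 1 null and 1 conditional allele of Ift88, which encodes a part of the intraflagellar transport machinery that builds cilia. Each mutant was thus heterozygous in all other cells of the organ, and the Cenpj control also served the Ift88 comparison. The labels do not say that replicates are separate animals, so each p-value measures only the spread between these libraries.

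The total of reads recovered from the deposited values ranged from 96.1 to 120.88 M reads per library. Barely detected genes most often held 12 to 42 reads rather than 1, depending on the library, and each total divided by that number came to between 2.32 M in intestine control 2 and 10.07 M in lung Cenpj mutant 4. Lung controls 1 to 4 held 110.3, 106, 96.1 and 108 M reads, lung Cenpj mutants 1 to 4 held 101, 112.4, 109.6 and 120.87 M reads, and lung Ift88 mutants 1 to 4 held 105, 120.88, 111 and 105 M reads. Intestine controls 1 to 4 held 100.4, 97.6, 113 and 104 M reads, intestine Cenpj mutants 1 to 4 held 109, 96.3, 109.5 and 106 M reads, and intestine Ift88 mutants 1 to 4 held 109, 108, 115 and 114 M reads. Between 21994 and 26529 genes were detected per library. The libraries were of 2 kinds. In 10 of them, ribosomal RNA genes took 2519 to 14428 reads per M reads and the small nuclear RNA Rn7sk reached 975 to 7113 normalized counts. The other 14 held 297 to 1287 ribosomal reads per M reads and 0 to 248 normalized counts of Rn7sk. All 8 Cenpj mutant libraries, lung control 3 and intestine control 2 were of the first kind, called ribosomal-rich here, while all 8 Ift88 mutant libraries were of the second. Levels of Xist and the Y-linked Ddx3y marked lung control 1 and intestine control 1 as male and intestine Cenpj mutant 1 as a mixture of both sexes, with 98518 normalized counts of Xist and 1438 of Ddx3y. The other 21 libraries were female.

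**Figure D1:**
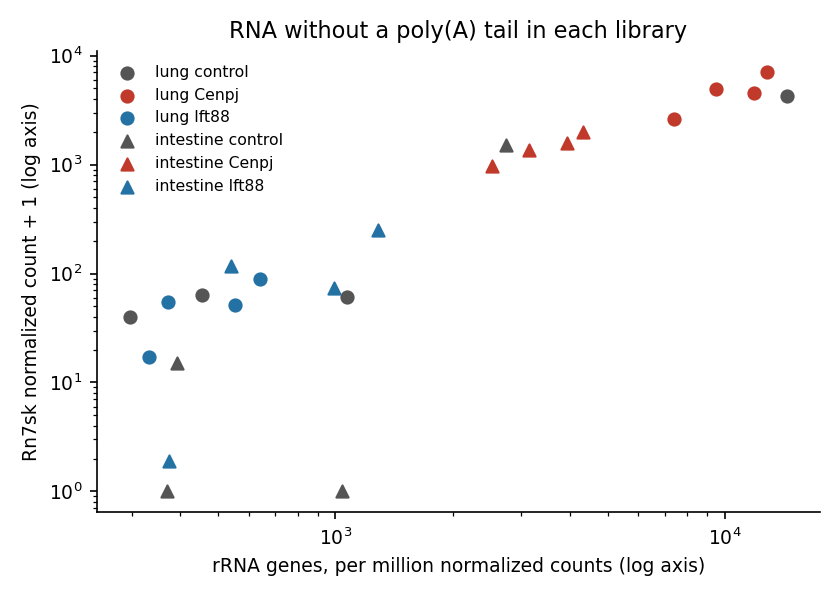
Ribosomal RNA reads per M reads (x axis, log scale) against Rn7sk normalized counts plus 1 (y axis, log scale) in each of the 24 libraries, with color for genotype, circles for lung and triangles for intestine. The 10 libraries at the upper right are the 8 Cenpj mutants, lung control 3 and intestine control 2.

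The targeted genes were examined first. Cenpj (ENSMUSG00000064128) lies on chromosome 14 at 56526761 to 56575425 and Ift88 (ENSMUSG00000040040) on the same chromosome at 57424062 to 57517936 in GRCm38. Cenpj averaged 3432.5 ± 819.9 normalized counts (SD, n = 4) in control lung, 2577 ± 339.5 in Cenpj mutant lung and 3326 ± 293 in Ift88 mutant lung. In intestine the means were 3552 ± 771 in controls, 2601 ± 434 in Cenpj mutants and 3137 ± 334 in Ift88 mutants. The Cenpj log2 fold change in Cenpj mutants was -0.39 (SE 0.16, adjusted p = 0.339) in lung and -0.44 (SE 0.156, adjusted p = 0.878) in intestine. Ift88 averaged 2637 ± 309 normalized counts in control lung, 2818 ± 346 in Cenpj mutant lung and 1973 ± 319 in Ift88 mutant lung. The intestine means of Ift88 were 2572 ± 202, 2792 ± 83.0 and 1981 ± 272 in the same order. In Ift88 mutants the Ift88 log2 fold change was -0.42 (SE 0.139, adjusted p = 0.166) in lung and -0.38 (SE 0.126, adjusted p = 0.155) in intestine. Group means were thus lowest in the matching mutant for both genes in both organs. None of the 4 differences passed the test over all genes, which is strict for genes named beforehand. Without lung control 4, which had the lowest Cenpj of the lung controls at 2259 normalized counts, the Cenpj difference in lung was -0.58 with an adjusted p of 0.0353. In the authors' deposited table the Ift88 fold in Ift88 mutants was 0.748 (FDR 0.0276) in lung and 0.77 (FDR 0.0498) in intestine. For Cenpj in Cenpj mutants, the authors' deposited table gave folds of 0.751 (FDR 0.15) in lung and 0.732 (FDR 0.473) in intestine.

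**Figure D2:**
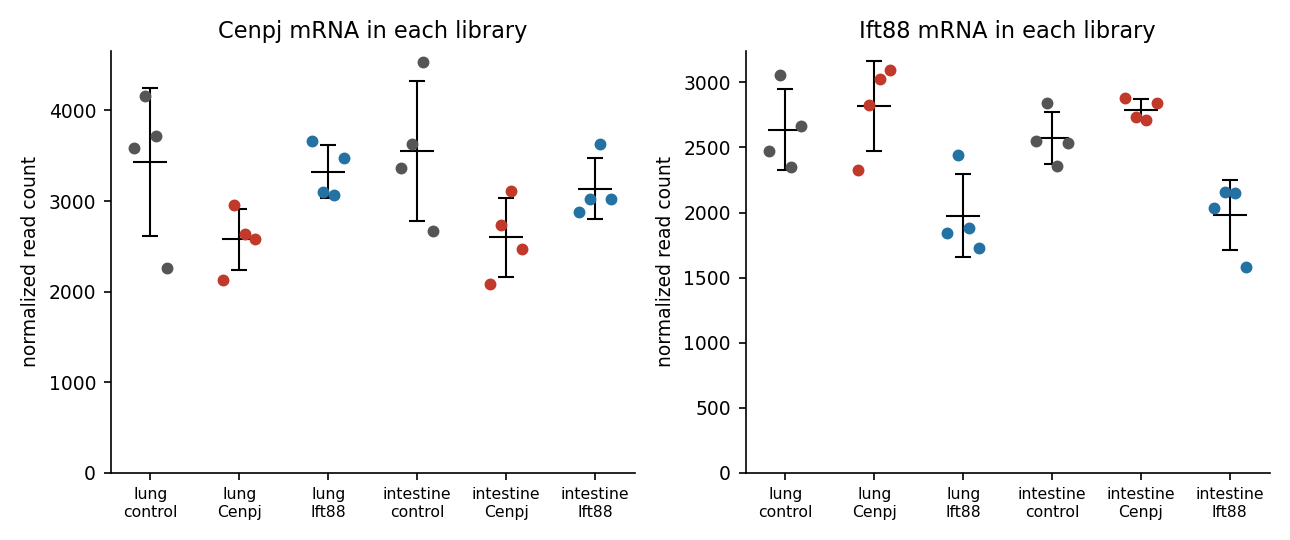
Normalized counts of Cenpj and of Ift88 (y axes) in each library of the 6 groups (points), with bars for the group mean and error bars for 1 SD (n = 4). Mean Cenpj is lowest in Cenpj mutants and mean Ift88 lowest in Ift88 mutants of both organs.

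The first comparison asked how loss of centrioles from the epithelium altered gene expression in the lung. Of 46 measured targets of the tumour suppressor p53, 5 rose in Cenpj mutant lung. Cdkn1a, encoding an inhibitor of cyclin-dependent kinases, increased from 692 ± 212 to 2772 ± 1413 normalized counts (log2 fold change 1.92, SE 0.315, adjusted p = 0.00682). Eda2r, a receptor of the tumour necrosis factor family, rose from 246 ± 47.5 to 1116 ± 520.0 (2.06, adjusted p = 0.00624), and the cyclin G gene Ccng1 rose from 4522 ± 849.6 to 9970.2 ± 2680.0 (1.11, adjusted p = 0.00578). Each of these 3 genes was higher in all 4 Cenpj mutant libraries than in all 4 controls. Transcripts of the hedgehog target Hhip, an inhibitor of hedgehog ligands, fell from 7879 ± 764.5 to 4693 ± 759.5 (-0.76, adjusted p = 0.00682).

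The 5 p53 targets that rose over all genes tested were Cdkn1a, Eda2r, Ccng1, Dcxr and Exoc4, none fell and 41 did not pass, while 16 rose when adjusted over the list alone. The mean log2 fold change of the p53 list was 0.585 and its median 0.304 (list test adjusted p = 8.64e-15, adjusted p = 0.108 with an estimated correlation). Among targets that did not pass over all genes, Ddit4l changed by 1.73 (adjusted p = 0.0546), the pro-apoptotic gene Pmaip1 by 3.27 (adjusted p = 0.0975), Ak1 by 0.64 (adjusted p = 0.0762) and Phlda3 by 0.53 (adjusted p = 0.0763). The 4 Cenpj mutant lungs stood 0.768, 0.764, 0.276 and 0.532 above the controls in the mean of the list. Each control lung set against its other 3 lay between -0.157 and 0.203. Genes that act in apoptosis, 22 measured, had a mean of 0.319 (list test adjusted p = 0.00321, adjusted p = 0.227 with an estimated correlation). None of them passed over all genes and only Pmaip1 passed when adjusted over the list alone, with Casp8 at 0.36 and Bax at 0.26. Senescence-associated genes, 12 measured, had a mean of 0.380 (adjusted p = 0.00938, adjusted p = 0.15 with an estimated correlation), with Cdkn1a and the lysosomal galactosidase gene Glb1 (0.49, adjusted p = 0.0414) rising both over all genes and when adjusted over the list alone.

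**Figure D3:**
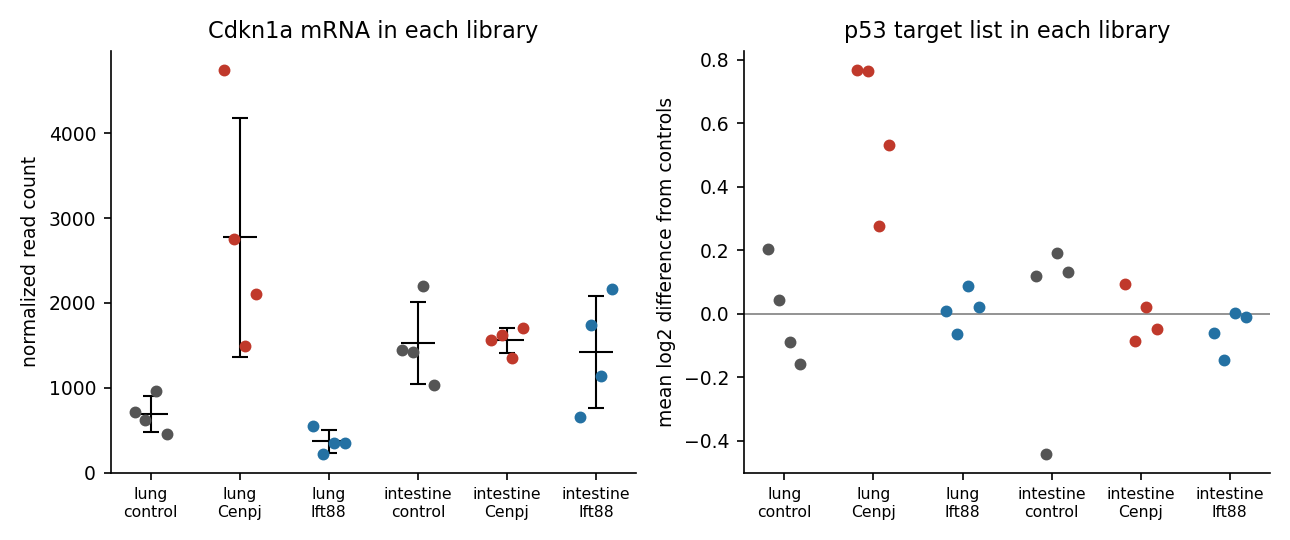
Left, Cdkn1a normalized counts (y axis) in each library of the 6 groups (points), with the group mean and SD (n = 4). Right, mean log2 difference of the 46 p53 targets (y axis) of each library from the controls of its organ, each control being set against its other 3 controls; the 4 Cenpj mutant lungs lie between 0.276 and 0.768.

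Some hedgehog and Wnt targets fell in the same comparison. Of 18 measured hedgehog targets, Hhip and the transcription factor gene Gli1 (18379 ± 1234 to 11996 ± 2977, log2 fold change -0.65, adjusted p = 0.0449) fell and 16 did not pass. The receptor gene Ptch1 (-0.60, adjusted p = 0.0762) passed only when adjusted over the list alone, where 4 fell and 1, Nkx2-3, a gene nearly absent from control lung, was higher. The list mean was -0.06 and its median -0.18 (adjusted p = 0.00321, adjusted p = 0.29 with an estimated correlation). Wnt targets, 14 measured, had a mean of -0.44 (adjusted p = 3.21e-05, adjusted p = 0.227 with an estimated correlation). Rnf43, a receptor-degrading ubiquitin ligase gene picked after its value was seen, fell by 0.67 (adjusted p = 0.0373) and 6 fell when adjusted over the list alone. Of 17 lung epithelial genes (mean -0.40, adjusted p = 0.00963, adjusted p = 0.467 with an estimated correlation) none passed over all genes. When adjusted over that list alone 3 were lower, namely Nkx2-1 at -0.99, Sox2 at -2.43 and Irx2 at -0.86. The 9 proximal airway genes averaged -1.41 (adjusted p = 0.00271, adjusted p = 0.108 with an estimated correlation), with Sox2 alone passing when adjusted over the list alone and none over all genes. Leaving out 1 library could end the call of the lung epithelial list, whose adjusted p was 0.0824 without lung control 1, 0.105 without lung control 3 and 0.27 without lung Cenpj mutant 4. The apoptosis list stood at 0.0548 without lung Cenpj mutant 1.

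Ribosomal protein genes, 30 measured, had a mean of 0.246 (adjusted p = 4.76e-09, adjusted p = 0.467 with an estimated correlation). None passed over all genes, and 3 passed when adjusted over the list alone, among them Rplp0 (0.47) and Rpl8 (0.33). Mitotic genes (25 measured, mean 0.109, adjusted p = 0.00143, adjusted p = 0.273 with an estimated correlation) and replication genes (24 measured, mean 0.0871, adjusted p = 0.00506, adjusted p = 0.467 with an estimated correlation) held no member that passed by either count. Without lung Cenpj mutant 3 the replication list stood at an adjusted p of 0.148. Macrophage genes, 13 measured, averaged 0.448 (adjusted p = 2.26e-05, adjusted p = 0.287 with an estimated correlation). The complement gene C1qc, picked after its value was seen, rose by 0.83 (adjusted p = 0.0463) and 4 rose when adjusted over the list alone (C1qc, C1qa, C1qb and Csf1r).

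Beyond these lists, the largest rises by the naming rule were in Klhdc7a (2.004), the surfactant protein gene Sftpb (1.15, but -0.429 with library kind as a term over 24 libraries, adjusted p = 0.972), Wdr83os (0.65), the intermediate filament gene Vim (0.63, from 62050.1 ± 7051 to 95646 ± 6606), Cpped1 (0.60) and the protease gene Ctsc (0.59). The largest falls were in the kinesin gene Kif12 (-1.89, from 1046 ± 450.2 to 271 ± 105), Sbsn (-1.72), Mast1 (-1.68), the pancreatic transcription factor gene Rbpjl (-1.51), Gdpd3 (-1.46), Rgs11 (-1.41), the kinase gene Lmtk3 (-1.30, from 7324 ± 964 to 3009.7 ± 641), the collagen gene Col7a1 (-1.29), Shisa7 (-1.28) and Ly6h (-1.27).

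In total limma called 161 genes of 31361 tested in Cenpj mutant lung, 25 higher and 136 lower, and 3606 had an unadjusted p under 0.05. The count was 49 with a sex covariate, 69 with only the 2 groups fitted, 86 with no filter beyond 1 read and 754 with DESeq2. As lists, 18 of 44 passed, 10 upward and 8 downward, and 0 with an estimated correlation. The authors' deposited table called 814 genes, 312 higher and 502 lower, and 151 genes were shared, all in the same direction. All 4 Cenpj mutant lungs and 1 of 4 control lungs were ribosomal-rich, so genotype and library kind largely coincided. With library kind as a term over all 24 libraries, a setting chosen after the data were seen, 83 genes were called, 71 higher and 12 lower, and within the lung the term gave 533. In that setting 2 of the 136 lower genes and 1 of the 25 higher genes kept their call, Lmtk3 stood at -0.97 (adjusted p = 0.0744) and Gli1 at -0.37 (adjusted p = 0.6). The p53 list had a mean of 0.784 there (adjusted p = 1.18e-13) and Ccng1 stayed called at 1.09 (adjusted p = 0.0188). Cdkn1a (1.679), Eda2r (2.278) and Hhip (-0.405) lost their calls (adjusted p = 0.118, 0.0674 and 0.709). The term within the lung ended all 4 calls (Ccng1 adjusted p = 0.0879). Lost calls alone do not implicate library kind. The count of 161 depended on single libraries: it was 68, 36 and 407 without lung control 1, 2 or 4, 74, 100 and 85 without Cenpj mutant 2, 3 or 4, and 88 and 85 without Ift88 mutant 1 or 2. Of 26 named genes called here, 8 kept their call whichever library was left out: Ccng1, Cdkn1a, Eda2r, Vim, Col7a1, Hhip, Kif12 and Lmtk3.

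The same question in the small intestine gave no called gene. Cdkn1a averaged 1529 ± 489 normalized counts in control and 1561 ± 148 in Cenpj mutant intestine (log2 fold change 0.08, adjusted p = 1). Ccng1 changed by 0.26 and Eda2r by 0.68, neither past the test, and the hedgehog targets Gli1 and Ptch1 stood at -0.34 and -0.29 without passing. These turned to 0.208 and 0.275 with library kind as a term within the organ, and Cdkn1a to -0.163 over 24 libraries, none of them passing. The 46 p53 targets had a mean of -0.00514 and a median of 0.0645 (list test upward, adjusted p = 0.71; mean 0.325 with library kind as a term within the organ and 0.194 with it over 24 libraries, adjusted p = 0.481 and adjusted p = 0.508). Of the controls, ribosomal-rich intestine control 2 stood at -0.441 in the mean of the list against its other 3. None of the 46 passed over all genes or when adjusted over the list alone. Since fewer than 5 genes qualified, the naming rule gives the 5 with the smallest p, which were the synaptic gene Lgi2 (-0.53), the germ cell gene Ybx2 (-0.69), the Wnt inhibitor gene Sfrp2 (1.15), Mir5125 (-1.02) and Zfp692 (-0.67), with adjusted p values of 0.355 for the first 4 and 0.481 for Zfp692.

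Of 31592 genes tested in that comparison limma called 0, with 1616 at an unadjusted p under 0.05. On the same libraries edgeR called 0, limma-voom 1 and DESeq2 54, and with library kind as a term limma called 568 within the organ and 85 over 24 libraries. The authors' deposited table listed 93, 43 of them higher and 50 lower. None of 44 lists passed. Of 200 changes simulated here, limma found 48% at 2-fold and 88% at 4-fold, not a rate for all 29504 genes. The count stayed at 0 to 1 without any single library except intestine control 2, the ribosomal-rich control, without which 37 genes were called; without intestine Cenpj mutant 1 or 4 the count was 1.

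Whether the Cenpj effect differed between the organs was tested directly as an interaction. The p53 targets responded more strongly in lung: the difference between the organs averaged 0.59 over the list (adjusted p = 2.74e-12, and adjusted p = 0.0205 with an estimated correlation). Of its 46 members, 8 differed upward when adjusted over the list alone and none over all genes, with Cdkn1a at 1.84, Ccng1 at 0.85 and Dcxr at 1.43. Wnt targets differed by -0.62 on average (adjusted p = 5.62e-06, adjusted p = 0.133 with an estimated correlation), with Axin2 (-0.63) and Apcdd1 (-0.99) passing when adjusted over the list alone and none over all genes. Ribosomal protein genes (mean difference 0.325, adjusted p = 2.74e-12, adjusted p = 0.448 with an estimated correlation) and apoptosis genes (mean difference 0.311, adjusted p = 0.0192, adjusted p = 0.26 with an estimated correlation) had no member that passed by either count. The apoptosis list stood at an adjusted p of 0.0645 without lung control 3, 0.162 without lung Cenpj mutant 1, 0.0853 without intestine control 3 and 0.064 without intestine Cenpj mutant 1. Among the genes with the smallest p were the transcription factor gene Hlf (-1.44, adjusted p = 0.533) and Cdkn1a (adjusted p = 0.932). No single gene was called by limma among 32098 tested, 1528 had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 44. Of 44 lists 12 passed, and only the p53 list with an estimated correlation.

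The Ift88 comparison asked how loss of cilia from the epithelium altered the lung. A later stage of the Ift88 embryos, a candidate explanation given below for the globins, was not separated from genotype for any gene or list in either organ. Some red blood cell genes fell: the embryonic globin gene Hbb-bh1 dropped from 80102 ± 24369 to 9988 ± 2493 normalized counts (log2 fold change -2.99, SE 0.216, adjusted p = 6.09e-07), and the erythroid gene Hemgn from 3356 ± 2476 to 238 ± 183 (-3.76, adjusted p = 0.000826). The surfactant gene Sftpc, a marker of distal lung epithelium, rose from 573 ± 353 to 3236 ± 172 (2.96, adjusted p = 0.00743). Smooth muscle actin genes rose as well, Acta2 by 2.23 (adjusted p = 0.00448) and Actg2 by 2.07 (adjusted p = 0.0158). Hbb-bh1, Hemgn, Sftpc and Acta2 separated all 4 mutant from all 4 control libraries, whereas Actg2 overlapped, with lung control 1 at 2600.0 and lung Ift88 mutant 3 at 2573.5.

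Of 14 erythroid genes, 6 fell over all genes, among them Hbb-bh1, the embryonic globin gene Hba-x (-1.96, adjusted p = 0.0054) and the master regulator gene Gata1 (-2.52, adjusted p = 0.026), and 9 fell when adjusted over the list alone. The list mean was -1.30 (adjusted p = 6.71e-13, adjusted p = 0.368 with an estimated correlation). How reads shared by near-identical globin genes were counted is not given in the sources used here. Smooth muscle genes (10 measured, mean 0.924, adjusted p = 8.59e-06, adjusted p = 0.368 with an estimated correlation) held 2 that rose, Acta2 and Actg2, and 6 when adjusted over the list alone. General epithelial genes (20 measured, mean 0.434, adjusted p = 7.54e-06, adjusted p = 0.469 with an estimated correlation) held none over all genes, while Ap1m2 (0.81), Epcam (0.75) and Rab25 (0.72) passed when adjusted over the list alone. Endothelial genes (15 measured, mean 0.168, adjusted p = 0.0317, adjusted p = 0.654 with an estimated correlation) held 3 that rose by both counts, Pecam1 (0.71), Egfl7 (0.46) and Esam (0.73). Macrophage genes (13 measured, mean 0.392, adjusted p = 0.000207, adjusted p = 0.431 with an estimated correlation) held C1qc, picked after its value was seen, at 0.78 over all genes and 5 when adjusted over the list alone (C1qc, Csf1r, Mrc1, C1qa and Fcer1g).

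Genes of gut mesenchyme (17 measured, mean -1.0004, adjusted p = 0.018, adjusted p = 0.368 with an estimated correlation) held 1 member that fell over all genes, and when adjusted over the list alone 6 were lower and 1, Hoxb8, higher at 1.45. Neural tube genes (9 measured, mean -1.20, adjusted p = 0.0165, adjusted p = 0.368 with an estimated correlation) held Nkx6-1 (-1.59, adjusted p = 0.0143) over all genes and also Isl1 (-0.84) and Zic1 (-3.59) when adjusted over the list alone. The 44 genes of intraflagellar transport and cilia had a mean of 0.0804 (adjusted p = 0.0419, adjusted p = 0.368 with an estimated correlation) and no member past the test by either count. Neither the hedgehog targets (mean -0.04, adjusted p = 0.171) nor the p53 targets (mean 0.01, adjusted p = 0.465) passed as lists. Single libraries ended some of these calls. The endothelial list stood at adjusted p values of 0.235, 0.225, 0.156 and 0.372 without lung control 2, control 4, Ift88 mutant 1 or Ift88 mutant 4. For the gut mesenchyme list the value was 0.0574 without control 2, and for the neural tube list 0.0526 without control 3 and 0.051 without Ift88 mutant 4. The cilia list stood at 0.0574, 0.0526 and 0.0726 without control 2, 3 or 4 and at 0.0861, 0.0755 and 0.0661 without Ift88 mutant 1, 2 or 3.

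The other large rises were in Calb2 (3.34), Aldh1a7 (3.04), the extracellular matrix gene Lum (3.01), the growth factor gene Vegfd (2.68), Kcne4 (2.51), the cation channel gene Trpm5 (2.48), the chloride channel gene Cftr (2.29), Arhgap20 (2.25) and the water channel gene Aqp4 (2.24). The other large falls were in the transcription factor gene Tfap2b (-3.86), Col8a1 (-3.47), the kidney progenitor gene Six2 (-3.28), Adra2b (-3.25), the pyruvate kinase gene Pklr (-3.04), Slc30a10 (-2.99) and Slc24a2 (-2.58). List members by the rule included Wnt2 (0.82), a ligand of lung mesenchyme, and Plk2 (0.88), which rose. Twist1 (-2.23), Foxp1 (-1.02, from 29536 ± 6510.4 to 14346.5 ± 1257.5), Hsd11b2 (-1.24, from 9409 ± 3127 to 3835 ± 388) and Il17rd (-0.64), an inhibitor of growth factor signalling, fell.

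**Figure D4:**
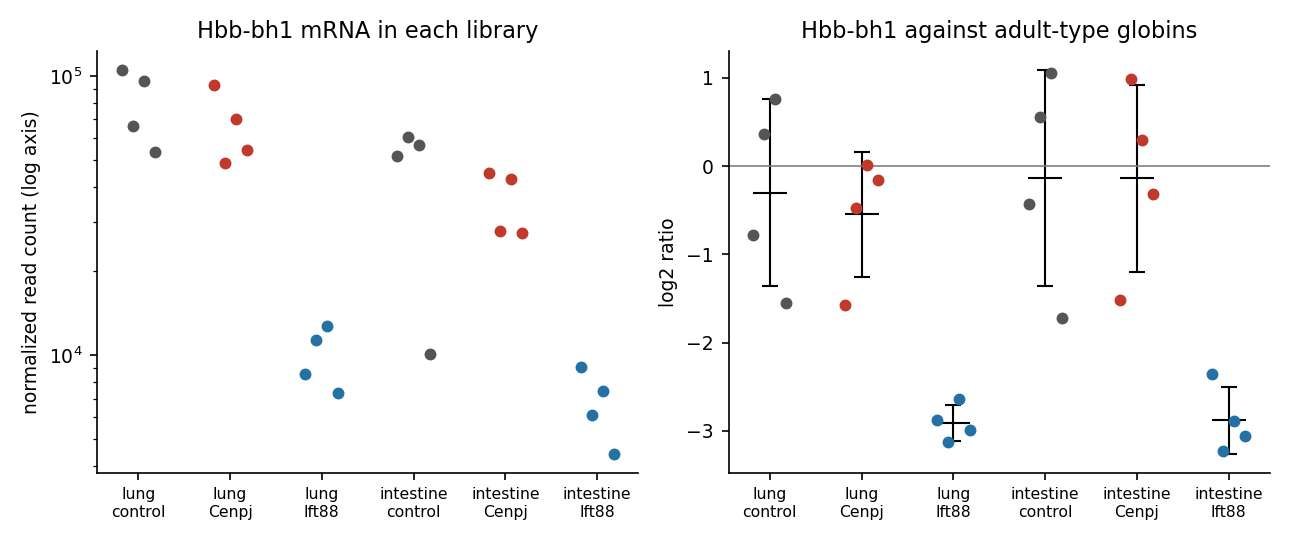
Left, Hbb-bh1 normalized counts (y axis, log scale) in each library of the 6 groups (points). Right, log2 ratio of Hbb-bh1 to the summed adult-type globins (y axis) per library with the group mean and SD (n = 4); Ift88 mutants average -2.91 in lung and -2.88 in intestine.

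limma called 335 genes in Ift88 mutant lung, 137 higher and 198 lower, with 3837 at an unadjusted p under 0.05. The count was 90 with a sex covariate, 150 with no filter beyond 1 read, 191 with edgeR scaled by library size only and 972 with DESeq2. Of 44 lists 11 passed, and 0 with an estimated correlation. The authors' deposited table called 996, with 351 higher and 645 lower, and 280 were shared. The split between higher and lower calls was 168 and 169 in limma with equal library totals and 63 and 169 with edgeR, which differs in its test and gene filter as well. All 4 mutants and 3 of the 4 controls were of the kind with little ribosomal RNA, and with library kind as a term 16 genes were called within the organ and 263 over all 24 libraries. The count was 222, 149, 99 and 995 without lung control 1, 2, 3 or 4 and 52, 73 and 194 without Ift88 mutant 1, 2 or 3. Of 35 named genes called here, 11 kept their call whichever library was left out, namely Hbb-bh1, Hba-x, Hemgn, Sftpc, Acta2, Aqp4, Cftr, Calb2, Aldh1a7, Foxp1 and Slc30a10. Of these 11, Sftpc, Acta2, Calb2 and Aqp4 lost their call with library kind as a term over 24 libraries (adjusted p = 0.184, 0.298, 0.347 and 0.075). So did Actg2 and the smooth muscle list (adjusted p = 0.409 and 0.0596). These losses alone do not implicate library kind.

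In Ift88 mutant intestine 2 of 14 erythroid genes fell and 2 of 10 smooth muscle genes rose over all genes. Hbb-bh1 fell from 44844 ± 23441 to 6773 ± 1957 normalized counts (log2 fold change -2.48, SE 0.402, adjusted p = 0.0101) and Hemgn from 1451 ± 730 to 129 ± 97.4 (-3.68, adjusted p = 0.00392). Acta2 rose from 17365 ± 25776 to 93275 ± 24625 (3.83, adjusted p = 0.0482), with intestine control 4 alone at 55733 among the controls. The largest drop in relation to its spread was in the metalloprotease gene Adamts18, from 3788 ± 1012 to 829.9 ± 204 (-2.18, SE 0.202, adjusted p = 7.68e-05). Etv5, a target of growth factor signalling through ERK, fell from 7048 ± 1905 to 3239.7 ± 1413 (-1.16, adjusted p = 0.0341).

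Neural crest and enteric neuron genes, 16 measured, had a mean of 1.14 (adjusted p = 6.47e-11, adjusted p = 0.326 with an estimated correlation). The stathmin genes Stmn2 (1.95, from 1847 ± 1527 to 5655 ± 513) and Stmn3 (2.07) rose over all genes, 14 did not pass, and 11 rose when adjusted over the list alone. Of 10 smooth muscle genes (mean 2.002, adjusted p = 4.36e-05, adjusted p = 0.334 with an estimated correlation) Acta2 and Cnn1 (3.42) rose over all genes and 6 when adjusted over the list alone. Mesothelial genes (10 measured, mean 1.17, adjusted p = 2.02e-05, adjusted p = 0.326 with an estimated correlation) held Krt19, picked after its value was seen, at 1.29 over all genes and 6 when adjusted over the list alone. ERK targets, 22 measured, averaged -0.28 (adjusted p = 9.88e-07, adjusted p = 0.326 with an estimated correlation). Etv5 and the cyclin gene Ccnd1 (-0.48, adjusted p = 0.0458) fell over all genes and 10 when adjusted over the list alone, with Etv4 at -0.94 (adjusted p = 0.095) and Dusp6 at -0.57 (adjusted p = 0.124). Replication genes (24 measured, mean -0.21, adjusted p = 5.64e-08, adjusted p = 0.326 with an estimated correlation) held none over all genes and Rrm2 (-0.60) and Uhrf1 (-0.45) when adjusted over the list alone. Mitotic genes (25 measured, mean -0.14, adjusted p = 2.84e-06, adjusted p = 0.326 with an estimated correlation) held none by either count. Endothelial genes (15 measured, mean -0.37, adjusted p = 1.76e-06, adjusted p = 0.351 with an estimated correlation) held none over all genes and 6 that fell when adjusted over the list alone. Erythroid genes (14 measured, mean -0.76, adjusted p = 1.76e-06, adjusted p = 0.326 with an estimated correlation) held 2 that fell over all genes, Hbb-bh1 among them, and 8 when adjusted over the list alone. Gut mesenchyme genes (17 measured, mean -1.13, adjusted p = 0.000108, adjusted p = 0.326 with an estimated correlation) held Hand1 (-0.79) and Nkx3-2 (-0.74), which fell by both counts. With library kind as a term over 24 libraries Hand1, Nkx3-2, Stmn3, Etv5, Ccnd1 and Krt19 lost their calls (adjusted p = 0.832, 0.75, 0.412, 0.0915, 0.11 and 0.0569). So did the gut mesenchyme list (adjusted p = 0.0578). Such losses alone do not implicate library kind.

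The other large rises were in the retinoic acid synthesis gene Aldh1a1 (4.21), the milk-clotting protease gene Cym (3.73), Nfix (3.49), Trpm5 (3.10), the keratin gene Krt15 (2.95), Npas4 (2.91), the collagen receptor gene Ddr2 (2.64) and Cryab (2.34). The other large falls were in the glucagon gene Gcg (-3.33), Slc38a5 (-2.52), Oacyl (-2.24), Nwd2 (-2.15), Igdcc3 (-2.02), the serum amyloid gene Saa2 (-2.02) and the cytokine receptor gene Csf2rb (-2.01). Hsd11b2, which inactivates glucocorticoids, fell by 1.97 (from 13102 ± 4963.5 to 3144 ± 669).

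In all, limma called 227 genes of 31592 in Ift88 mutant intestine, 126 higher and 101 lower, with 4234 at an unadjusted p under 0.05. The count was 69 with no filter beyond 1 read, 150 without the male and mixed libraries, 527 with all 24 libraries in one fit and 1015 with DESeq2. Of 44 lists 16 passed, and 0 with an estimated correlation. The authors' deposited table called 1126, with 482 higher and 644 lower, and 192 were shared. The split differed between tools, at 254 higher and 111 lower with limma-voom and 36 higher and 56 lower with edgeR. With library kind as a term 31 genes were called within the organ and 239 over all 24 libraries, 144 higher and 95 lower. Without intestine control 1, 2, 3 or 4 the count was 43, 108, 25 or 1027, without Cenpj mutant 2, 3 or 4 it was 374, 125 or 123, and without Ift88 mutant 1, 2 or 3 it was 33, 36 or 29. Of 28 named genes called here, Adamts18, Hemgn, Hsd11b2, Nwd2 and Saa2 kept their call whichever library was left out, and Hbb-bh1 lost it only without control 3 (adjusted p = 0.0529).

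The Ift88 effect differed between the organs in 4 genes. Cyp1b1, a cytochrome P450 gene of retinoid and steroid metabolism, went from 4135 ± 1254 to 1596 ± 296 normalized counts in lung and from 1005 ± 299 to 1904 ± 552 in intestine (difference -2.27, adjusted p = 0.0197). The endothelial matrix gene Mmrn1 went from 5237 ± 1046 to 8698 ± 556 in lung and from 1869.7 ± 394 to 923 ± 203 in intestine (difference 1.77, adjusted p = 0.0235). The ligand gene Wnt3 averaged 113 in control and 11 in Ift88 mutant lung, where only mutant 2 held any, and 0.5 in control and 38.4 in mutant intestine (adjusted p = 0.0433), so its fold rests on values near 0. Gm14014 also passed (-5.49, adjusted p = 0.0235) and was picked after its value was seen. Slc38a5 (3.54) and Ephb1 (-1.89, adjusted p = 0.0535) did not pass.

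Neural crest and enteric neuron genes differed by -1.89 on average between the organs (adjusted p = 1.43e-15, adjusted p = 0.176 with an estimated correlation), and 11 of 16 differed when adjusted over the list alone. Endothelial genes differed by 0.539 (adjusted p = 4.97e-10, adjusted p = 0.204 with an estimated correlation), with Egfl7, Pecam1, Cldn5, Sox17 and Tek passing when adjusted over the list alone. ERK targets differed by 0.283 (adjusted p = 0.00287, adjusted p = 0.398 with an estimated correlation), with Etv5 (1.56) and Etv4 (1.09) passing when adjusted over the list alone. Replication genes (0.246, adjusted p = 4.97e-10, adjusted p = 0.201 with an estimated correlation) and mitotic genes (0.154, adjusted p = 8.77e-06, adjusted p = 0.201 with an estimated correlation) had no member past the test, and in none of these 5 lists did a member pass over all genes. limma called 4 genes of 32098, 1 higher and 3 lower, with 2334 at an unadjusted p under 0.05, while edgeR called 1 with DESeq2-type factors, 1 with library size only and 7 with TMM factors, the last chosen after the data were seen, and DESeq2 called 194. The count was 14 with a sex covariate and 26 with only the groups compared. With the replicate number as a block 22 genes were called, Slc38a5 and Etv5 passed (adjusted p = 0.0356 each) and Gm14014 did not (adjusted p = 0.0561). Leaving out 1 library moved the count between 0 (lung control 2, lung control 3, lung Ift88 mutant 1 or intestine control 3) and 135 (intestine control 4), and none of the 4 genes kept its call throughout. It was 1 without lung Ift88 mutant 4 or intestine control 2, 2 without lung control 1 or intestine Ift88 mutant 4, 8 without lung Ift88 mutant 3, 18 without lung Cenpj mutant 3, 35 without lung control 4 and 45 without lung Cenpj mutant 1. Of 44 lists 12 passed, and 0 with an estimated correlation.

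Cenpj and Ift88 mutants were compared directly to separate loss of centrioles from loss of cilia alone, although a difference in stage was not separated from genotype here either. In lung, p53 targets were higher in Cenpj mutants: 7 of 46 were higher over all genes, with Cdkn1a at 2.84 (adjusted p = 0.000104), Eda2r at 1.80, Perp at 1.56, Ccng1 at 0.97, Ak1 at 0.90, Sulf2 at 0.66 and Exoc4 at 0.40. When adjusted over the list alone 18 were higher and 1, Kank3, lower (list mean 0.572, adjusted p = 5.51e-11, adjusted p = 0.134 with an estimated correlation). Erythroid genes were higher in Cenpj mutants (14 measured, mean 1.11, adjusted p = 6.23e-10, adjusted p = 0.332 with an estimated correlation), with 4 passing over all genes, among them Hbb-bh1 (2.73), Hba-x (1.90) and Gata1 (2.33), and 8 when adjusted over the list alone. General epithelial genes were lower (20 measured, mean -0.65, adjusted p = 7.43e-10, adjusted p = 0.392 with an estimated correlation), with Epcam (-0.87), Esrp2 (-1.29) and Foxa1 (-1.48) over all genes and 10 when adjusted over the list alone. Genes of multiciliated cells averaged -1.20 (10 measured, adjusted p = 0.00779, adjusted p = 0.134 with an estimated correlation), with Ccno, picked after its value was seen, at -3.53 over all genes and also Mcidas when adjusted over the list alone. Of the hedgehog targets 3 were lower over all genes, Gli1 (-0.73) and Hhip (-0.52) among them, as were the lung epithelial genes Nkx2-1 (-1.50) and Sftpc (-2.31), while Foxp1 was higher (0.81). With library kind as a term Sftpc turned to 0.914 within the lung (adjusted p = 0.725) and stood at -0.696 over 24 libraries (adjusted p = 0.93), and Kank3 turned to 0.013 within the lung. The largest positive differences were in Rn7sk (6.63), Mir6236 (3.69), Hemgn (3.59), Lars2 (3.07), Lmx1a (2.97) and Foxd3 (2.53). Rn7sk is an RNA without a poly(A) tail, Mir6236 and Lars2 hold stretches resembling ribosomal RNA, and how such reads were assigned is not given. Mir6236 and Lars2 turned to -0.955 and -0.512 with library kind as a term within the lung, and Rn7sk to -1.163 with it over 24 libraries. Rn7sk averaged 4804 ± 1855 in Cenpj mutant and 52.4 ± 29.8 in Ift88 mutant lung. Cldn10 (-4.32), Aldh1a7 (-3.62), Kif12 (-2.93), Cckar (-2.49), Rgs11 (-2.48), Ano9 (-2.48), Col4a4 (-2.46), the heart muscle gene Myh6 (-2.44), Aqp4 (-2.40) and Rbpjl (-2.37) were lowest.

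In intestine the largest mean difference among the lists described here was in smooth muscle genes. Of 10 smooth muscle genes 6 were lower in Cenpj mutants, including the myosin gene Myh11 (-5.65), Acta2 (-4.37), Actg2 (-4.22) and Cnn1 (-3.80), and 7 were lower and 1, Des, higher when adjusted over the list alone (mean -2.61, adjusted p = 4.11e-07, adjusted p = 0.356 with an estimated correlation). Neural crest and enteric neuron genes were lower (16 measured, mean -1.20, adjusted p = 8.94e-11, adjusted p = 0.356 with an estimated correlation), 6 over all genes, including Stmn2 (-2.12) and Stmn3 (-2.36), and 12 when adjusted over the list alone. Replication genes were higher in Cenpj mutants (24 measured, mean 0.271, adjusted p = 2.62e-10, adjusted p = 0.356 with an estimated correlation), with Mcm2 (0.43), Mcm3 (0.40) and Rrm2 (0.68) over all genes and 12 when adjusted over the list alone. ERK targets were higher (22 measured, mean 0.294, adjusted p = 4.03e-06, adjusted p = 0.356 with an estimated correlation), with Etv5 (1.04), Ccnd1 (0.61), Il17rd (0.72), Epha4 (0.80) and Dusp6 (0.71) over all genes. When adjusted over the list alone 9 ERK targets were higher and 1, Spry1, lower. Erythroid genes were higher (14 measured, mean 0.740, adjusted p = 3.07e-05, adjusted p = 0.356 with an estimated correlation), with 4 over all genes, among them Hbb-bh1 (2.41), Klf1 (1.78) and Hba-x (1.48). When adjusted over that list alone 8 were higher and 1, the adult globin gene Hbb-bs, lower. Tlx1 (4.41), a spleen transcription factor gene, Hemgn (3.84), Gcg (3.34), Foxc2 (2.95), Lin28a (2.73), Slc38a5 (2.55), Oacyl (2.496) and Lef1 (2.03) were higher. Aldh1a1 (-3.94), Cym (-3.92), the galectin gene Lgals4 (-3.63), Trpm5 (-3.14) and the intestinal transcription factor gene Isx (-1.22) were lower. The calls of the 5 lists given here ended with library kind as a term within the organ (adjusted p from 0.158 to 0.512). Des turned to -0.012 there and Cym to 0.318 with the term over 24 libraries. Ift88 itself was higher in Cenpj than in Ift88 mutants by 0.51 (adjusted p = 0.0429), against 0.52 (adjusted p = 0.0657) in lung.

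limma called 563 genes between the mutants in lung, 213 higher and 350 lower in Cenpj mutants, and 692 in intestine, 311 higher and 381 lower, with 3797 and 4937 at an unadjusted p under 0.05. Of these, 473 and 611 were among the 1137 and 1998 of the authors' deposited table. Genotype and library kind coincided completely in both direct comparisons, and with library kind as a term over 24 libraries, which the controls inform, 36 and 22 genes were called; within the organ the term gave 285 and 368. DESeq2 called 1105 and 1855, and in intestine the count was 375 with no filter beyond 1 read, 404 with edgeR scaled by library size only, 1133 with all 24 libraries in one fit and 1492 with only the 2 groups fitted. In lung the count was 331, 324 and 297 without Cenpj mutant 2, 3 or 4 and 195, 228 and 279 without Ift88 mutant 1, 2 or 4. In intestine it was 1221 without control 2, 84 and 71 without Cenpj mutant 2 or 3, and 222, 91 and 157 without Ift88 mutant 1, 2 or 3. Of 35 named genes called in lung 21 kept their call whichever library was left out, Cdkn1a, Ccng1 and Eda2r among them, and in intestine Hbb-bh1, Hemgn and Lgals4 of 31 did.

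Because both mutants were set against the same controls, their shared calls were compared with chance. In lung 9 genes were called in both, 6 higher (Tubb6, Plin2, Sftpb, C1qc, Tmem176a and Zfp637) and 3 lower (Zdbf2 and Plxna2 among them), all in the same direction and, apart from Sftpb, picked after their values were seen. Independent lists would share 0.109 higher and 0.859 lower. Unchanged groups simulated against the same controls shared 0.02 on average and 1 at most. Those simulated groups held no changed genes and so had little to share. They cannot show how many of the real calls would be shared through the controls alone. The fold changes of the 2 mutants correlated across genes at 0.435 with a covariance of 0.442, against 0.5003 and 0.403 in the simulation, and genes are not independent replicates. With the controls split so that each mutant had its own pair, the correlation lay between -0.058 and 0.0345, and 5 of 6 splits shared 0 or 1 genes while the remaining split shared 9. In intestine 0 genes were called in both, since limma called 0 in the Cenpj comparison, with a covariance of 0.439 against 0.408 simulated and split correlations between -0.091 and 0.036.

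Control lung and control intestine differed in the genes that mark the 2 organs. Nkx2-1, the transcription factor of lung epithelium, averaged 8957 ± 2169 normalized counts in lung and 3.5 ± 7.1 in intestine, whereas the gut mesenchyme gene Nkx2-3 averaged 0.5 ± 1.0 in lung and 8515 ± 1072 in intestine. Tbx4 (20900.0 ± 3561 against 321 ± 366) and Tbx5 (34248 ± 5492 against 708.5 ± 690.6), which pattern lung mesenchyme, were higher in lung by 7.53 and 7.78. The intestinal genes Isx (0 against 1076 ± 454) and Cdx2 (3.8 against 1419.8 ± 536) were nearly or fully absent from lung, and Sftpc (573 ± 353 against 0) from intestine. Hand1, a gut mesenchyme gene, averaged 38.2 in lung and 16290 ± 2276 in intestine (-8.76), and the hedgehog ligand gene Ihh 63.3 and 1509 (-6.30).

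Gut mesenchyme genes (17 measured, mean -3.79, adjusted p = 8.57e-17, adjusted p = 0.000993 with an estimated correlation) held 10 that were lower in lung, among them Hand1, Nkx3-2 (-9.31) and Barx1 (-6.17), and 1 that was higher, Osr1 (1.38). Of 20 intestinal epithelial genes (mean -3.62, adjusted p = 2.23e-11, adjusted p = 0.0016 with an estimated correlation) 9 were lower in lung, including Isx, Cdx2, Ihh and Onecut2 (-4.25), and Gata6 was higher (1.43). Lung epithelial genes (17 measured, mean 2.19, adjusted p = 1.32e-09, adjusted p = 0.0296 with an estimated correlation) held 8 higher in lung, including the ligand gene Wnt7b (4.19), and Id2 lower (-1.08). Lung mesenchyme genes (14 measured, mean 1.91, adjusted p = 5.9e-05, adjusted p = 0.00859 with an estimated correlation) held 8 higher in lung, including Tbx4, Tbx5 and Wnt2 (6.80), and Tcf21 (-1.32) and Pdgfra (-1.19) lower. Wnt targets were higher in lung (14 measured, mean 1.29, adjusted p = 8.57e-17, adjusted p = 0.00135 with an estimated correlation), 9 of them over all genes, including Lef1 (2.86), Tnfrsf19 (1.79) and Axin2 (1.17). Heart muscle genes were also higher in lung (16 measured, mean 1.19, adjusted p = 2.03e-07, adjusted p = 0.000993 with an estimated correlation), 7 over all genes including Tnnt2 (4.26), while Nkx2-5 was lower (-6.82). Adjusted over the list alone, the counts were 12 lower and 1 higher for gut mesenchyme, 13 lower and 1 higher for intestinal epithelium, 10 higher and 1 lower for lung epithelium, 9 higher and 3 lower for lung mesenchyme, 10 higher for Wnt targets, and 9 higher and 1 lower for heart muscle. Further genes higher in lung were Smpx (7.47), Cdh16 (7.35), Sftpb (6.25) and Mgp (5.90). Further genes lower in lung were Ugt2b34 (-8.87), Mab21l2 (-8.08), Ambp (-7.15) and the enteric neuron receptor gene Ret (-3.22). limma called 1711 genes of 32098, 835 higher and 876 lower in lung, with 4673 at an unadjusted p under 0.05 and 1539 shared with the 2077 of the authors' deposited table. Leaving out any 1 library gave counts from 1454 to 1799.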

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

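All tests that use library kind, directly or as a term, and those of blood content, of developmental stage, of the epithelial share and of the extent of Cenpj deletion, and the splits that part every same-numbered pair, were chosen only after the results were seen.

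Single libraries stood apart from the other 3 of their group in 13 of 115 groups tested, where chance gives about 5%. Lung control 3 held 14428.4 ribosomal reads per M reads against 296.9 to 1073.8 in the other lung controls, and 4296.9 normalized counts of Rn7sk against 39 to 63. Intestine control 2 held 1517.4 of Rn7sk against 0 to 14.1. Acta2 reached 55732.9 in intestine control 4 against 811 to 8590.9, Cyp1b1 2726.6 in intestine Ift88 mutant 2 against 1566.4 to 1703.8, Ihh 207.2 in lung control 3 against 0 to 30.5, and Mmrn1 7866.1 in lung Ift88 mutant 3 against 8921.9 to 9013.5. Intestine Cenpj mutant 2 had 22879 genes detected against 24939 to 25073. Near the floor, Nkx2-1 held 14.2 in intestine control 3, Nkx2-3 2 in lung control 4, Cdx2 15 in lung control 2, Wnt3 2 in intestine control 4 and Wnt3 44 in lung Ift88 mutant 2, with the other 3 libraries of each group at 0.

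The 2 organs differed in their response, by a test of the difference itself, in the following results. For the Cenpj mutants these were the mean of the p53 targets (0.59), of ribosomal protein genes (0.325), of Wnt targets (-0.622) and of apoptosis genes (0.311). With an estimated correlation the p53 call was kept (adjusted p = 0.0205), and those of ribosomal protein genes (adjusted p = 0.448), Wnt targets (adjusted p = 0.133) and apoptosis genes (adjusted p = 0.26) were lost. For the Ift88 mutants they were Cyp1b1 (-2.267), Mmrn1 (1.769), Wnt3 (-9.972), Gm14014 (-5.49) and the means of neural crest and enteric neuron genes (-1.894), replication genes (0.246), endothelial genes (0.539), ERK targets (0.283) and mitotic genes (0.154). With an estimated correlation all 5 of these list calls were lost, at adjusted p values of 0.176, 0.201, 0.204, 0.398 and 0.201.

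Other splits of the same libraries were run beside each count. The real split led for Cenpj mutant lung against control (1 of 35 splits, 161 genes against at most 124 in another split), for the mean of its p53 targets (1 of 35, 0.585 against at most 0.523) and for Ift88 mutant lung (1 of 35, 335 against at most 210). It also led for Cenpj against Ift88 mutants in lung (1 of 35, 563 against at most 1) and in intestine (1 of 35, 692 against at most 0), and for control lung against control intestine (1 of 35, 1711 against at most 40). Each met the limit set beforehand, a share under 0.05, but 1 of 35 is the smallest share that 4 against 4 can give. The shares were not adjusted for the number of results, so chance was made less likely for each alone but not excluded. Among the 8 splits of the control lung and control intestine libraries that part every same-numbered pair, too few for a share under 0.05, the highest other called 4. Ift88 mutant intestine did not meet the limit, as 2 of 35 splits gave as many genes, 227 against 425 when intestine control 2 was grouped with Ift88 mutants 1, 2 and 3. For Cenpj mutant intestine the count of splits (35 of 35) tells nothing, since any split calls at least 0 genes, but the split joining controls 1 and 4 with Cenpj mutants 1 and 4 gave 373, which points to a structure of the samples. For the Cenpj difference between organs the count (100 of 100) tells nothing for the same reason, with a highest other of 195, which points to a structure of the samples. Of the same 100 splits 2, the real one included, gave a difference in p53 targets as large as 0.590 (highest other 0.714). These splits shuffled mutants and controls within each organ and ignored the numbers that pair the controls. They stand for no effect in either organ, not for an equal effect in both, so they cannot test the difference between organs. For the Ift88 difference between organs 3 of 100 splits of the same kind gave 4 genes or more, the real one included. Another split gave 1175, which points to a structure of the samples, so chance was not excluded for that count.

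Most genes called in Cenpj mutant lung were lower than in control. With the trend on gene length and GC content removed, 85.4% of the median fall was kept (-0.72 to -0.62). Picking genes for large falls favours that, and these were longer (median exon length 6795 against 4053.5 of all), so both stay open. Library kind may account for much of the fall. The genes had a median of -0.542 in intestine control 2, the ribosomal-rich one, against the other 3 (129 of 136 negative). The others gave 0.149 to 0.218. Lung control 3 (ribosomal-rich) gave -0.131 and lung control 4 gave -0.166, but both helped pick the genes and cannot decide. Cenpj genotype alone and library kind cannot be told apart, because every Cenpj mutant library was ribosomal-rich: the same genes had a median of -0.372 in Cenpj mutant intestine, which either would give, and 0.0343 in Ift88 mutant intestine, and with library kind as a term over 24 libraries 2 of 136 genes were still called lower, and their median went from -0.72 to -0.47.

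The embryonic globin gene Hbb-bh1 and the erythroid gene Hemgn were lower in Ift88 mutants of both organs. Less blood alone would lower all globins alike, but the log2 ratio of Hbb-bh1 to adult-type globins was lower by a difference of -2.61 in lung (-2.91 ± 0.204 against -0.30 ± 1.06, n = 4 each) and -2.75 in intestine, each with an exact permutation p of 0.0286, the smallest that 4 against 4 can give. In Cenpj mutants the differences were -0.25 (exact p = 0.657) and -0.00148 (exact p = 1). A candidate explanation is that the Ift88 embryos were at a later stage, since genes of the Lin28 and let-7 axis, which fall as embryos age, had medians of -0.537 in lung and -0.544 in intestine, with 13 of 14 below 0 in each. The same genes had a median of -0.318 in Cenpj mutant lung, also with 13 of 14 below 0, and -0.0566 in Cenpj mutant intestine, and an effect of Ift88 itself stays open as untested.

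The p53 targets were higher in Cenpj mutant lung and not in Cenpj mutant intestine. Library kind was argued against by the mean of 0.784 with it as a term (0.585 without). Intestine Cenpj mutants cannot decide, holding less ribosomal RNA (2519 to 4332 per M reads against 7407.5 to 12862.5 in lung). Library kind may hide a rise in intestine, with the ribosomal-rich control at -0.441 from the other 3 and a mean of 0.325 with the term (adjusted p = 0.481). A smaller share of epithelium in the intestine was argued against by the general epithelial genes, which averaged 0.077 higher in control intestine than in control lung (SD over 20 members 0.589). Whether Cenpj was deleted less in the intestine cannot be told apart from a difference between the organs. The fall of Cenpj there was 113.5% of that in lung with a standard error of 61.9, and in both organs it may include a fall from the null allele in all other cells. A difference between the epithelia of the 2 organs in their response to centriole loss stays open as a hypothesis.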

How the results depend on the processing

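Library kind as a term, edgeR with TMM, limma after TMM scaling or with equal totals, and leaving out the male and mixed libraries were chosen only after the results were seen; the other alternatives were planned. No scaling moved the median of all genes by more than 0.1. Of 5559 repeats of named gene results 4601 kept direction and side of the threshold, 871 lost the call, 69 gained it and 18 reversed; of 1077 repeats of list results 935 kept theirs and 142 lost the call. When single libraries were left out, 3257 of 3972 gene repeats and 794 of 816 list repeats kept theirs, 649 and 22 lost the call, 51 and 0 gained it, and 15 and 0 reversed. Of 53 list results, 1 of them not called to begin with, 45 lost the call with an estimated correlation, 40 with directional fry and 20 with mixed fry. Except where fewer genes or samples are named as the reason, the cause was not tested. Whether depth or the spread between 4 libraries limited the calls was not tested; barely detected genes most often held 12 to 42 reads, so the totals may overstate the depth.

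Stricter thresholds lower counts by construction. At an adjusted p under 0.01 the counts were 42 (Cenpj mutant lung against control), 48 (Ift88 mutant lung), 168 (Cenpj against Ift88 in lung), 22 (Ift88 mutant intestine), 56 (Cenpj against Ift88 in intestine), 0 (Ift88 difference between organs) and 1073 (control lung against intestine). With an absolute log2 fold change of 1 or more they were 44, 163, 295, 123, 287 and, for the control organs, 1131.

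With no filter beyond 1 read, which tests more genes, counts were 86 for Cenpj mutant lung, 150 for Ift88 mutant lung, 69 (28 higher, 41 lower) for Ift88 mutant intestine, 375 for Cenpj against Ift88 in intestine and 2 for the Cenpj difference between organs. With CPM of 1 or more in at least 4 libraries the Ift88 difference was 2, and Ift88 mutant intestine split into 111 higher and 134 lower. limma-voom called 1 in Cenpj mutant intestine and 365 (254 higher, 111 lower) in Ift88 mutant intestine, and split Ift88 mutant lung into 142 and 116, Cenpj against Ift88 in lung into 163 and 482, and the Ift88 difference into 0 and 3. With equal totals the splits were 168 and 169, 186 and 496, and 2 and 3. edgeR with TMM called 92 (36 and 56) in Ift88 mutant intestine and 7 (1 and 6) for the Ift88 difference, with 63 and 169 in Ift88 mutant lung. edgeR with RLE called 105 (35 and 70) and 1 (0 and 1), with 292 and 223 for Cenpj against Ift88 in intestine. edgeR with library size only called 191 in Ift88 mutant lung, 93 (38 and 55) in Ift88 mutant intestine, 404 for Cenpj against Ift88 in intestine and 1 for the Ift88 difference, with 118 and 424 for Cenpj against Ift88 in lung. DESeq2 called 754 (264 and 490), 972 and 1105 in the lung comparisons in the order above, 54 in Cenpj mutant intestine, 1015 (394 and 621) in Ift88 mutant intestine, 1855 for Cenpj against Ift88 in intestine, and 44 and 194 for the Cenpj and Ift88 differences. Ift88 in Ift88 mutant intestine passed there at -0.387 (adjusted p = 0.0469).

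In control lung with control intestine all 4 same-numbered pairs correlated above 0.1 and 8 of 8 libraries correlated best with their own number, and control 1 was male in both organs. With the replicate block that comparison called 2082 genes, within 1.5 times of the main count, and it changed no other call there. The numbers did not pair the other groups: 13 of 48 libraries within an organ correlated best with their own number, with 3 of 4 pairs above 0.1 in intestine control with intestine Cenpj mutant. The differences between organs use the paired controls and mutants that were not paired by this check. With the replicate block counts were 506 for Ift88 mutant lung, 545 for Ift88 mutant intestine, 1151 for Cenpj against Ift88 in intestine and 22 for the Ift88 difference, where Slc38a5 and Etv5 passed (adjusted p = 0.0356 each) and Gm14014 did not (adjusted p = 0.0561). A sex covariate gave 49, 90 and 14 for Cenpj mutant lung, Ift88 mutant lung and the Ift88 difference. Without the male and mixed libraries, which leaves fewer samples, counts were 68, 222, 1 (Cenpj mutant intestine), 150 (Ift88 mutant intestine) and 2 (Ift88 difference). With only the groups of the comparison they were 69 for Cenpj mutant lung, 1492 for Cenpj against Ift88 in intestine and 26 for the Ift88 difference. With all 24 libraries in one fit they were 3, 527 and 1133 in the intestine comparisons, and Cenpj mutant lung split into 51 and 144.

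Library kind as a term within an organ, which rests on 1 ribosomal-rich control, gave 533 (332 and 201), 16 and 285 in lung and 568, 31 (14 and 17) and 368 (208 and 160) in intestine. Over all 24 libraries it gave 83 (71 and 12) and 36 (25 and 11) for Cenpj against control and against Ift88 in lung, 85 and 22 (16 and 6) in intestine, and split Ift88 mutant lung into 80 and 183. There 9 of 38 list results lost the call, against 12 of 53 list results with the term within an organ. The 9 were smooth muscle genes in Ift88 mutant lung (adjusted p = 0.0596), gut mesenchyme genes in Ift88 mutant intestine (0.0578), multiciliated genes for Cenpj against Ift88 in lung (0.246), and ribosomal protein genes (adjusted p = 0.56), hedgehog targets (0.219), senescence genes (0.421), mitotic genes (0.219), replication genes (0.814) and proximal airway genes (0.178) in Cenpj mutant lung. Within an organ the 12 were the last 4 of these lists, gut mesenchyme and neural tube genes in Ift88 mutant lung, multiciliated genes, and all 5 described for Cenpj against Ift88 in intestine. The p53 list in lung kept its mean of 0.585 with an estimated correlation but not its call (adjusted p = 0.108).

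Reversals with library kind as a term within an organ were Mir6236 (-0.955), Lars2 (-0.512), Sftpc (0.914) and Kank3 (0.013) for Cenpj against Ift88 in lung, Ift88 (-0.028), Gli1 (0.208) and Ptch1 (0.275) in Cenpj mutant intestine, and Des (-0.012) for Cenpj against Ift88 in intestine. Over all 24 libraries they were Sftpb in Cenpj mutant lung (-0.429), Rn7sk for Cenpj against Ift88 in lung (-1.163), Cdkn1a in Cenpj mutant intestine (-0.163) and Cym for Cenpj against Ift88 in intestine (0.318). Cenpj in Ift88 mutant lung, at -0.01, turned to 0.029 with limma-voom and with equal totals, 0.007 with the sex covariate, 0.037 with library kind, 0.021 with library kind over 24 libraries, 0.02 without the male and mixed libraries, and 0.019 to 0.092 when lung control 1, 2 or 3 or Ift88 mutant 2 or 3 was left out (from -0.202 without lung control 4 to 0.092 in all).

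Leaving out single libraries gave 36 to 407 genes for Cenpj mutant lung, 52 to 995 for Ift88 mutant lung, 195 to 681 for Cenpj against Ift88 in lung (195 to 331 where the count moved by over 1.5 times), 0 to 37 for Cenpj mutant intestine (1 to 37 where it moved), 25 to 1027 for Ift88 mutant intestine, 71 to 1221 for Cenpj against Ift88 in intestine, 0 for the Cenpj difference, 0 to 135 for the Ift88 difference and 1454 to 1799 for the control organs. Cenpj in Cenpj mutant lung lay between -0.576 and -0.282 and passed only without lung control 4 (-0.576, adjusted p = 0.0353). Cdkn1a in Cenpj mutant intestine lay between -0.091 and 0.271 and reversed without intestine control 4. The Ift88 difference of Ift88 itself lay between -0.146 and 0.034 and reversed without lung control 2, lung Ift88 mutant 4, intestine control 3 or intestine Ift88 mutant 2 or 3. The Cenpj difference of Cenpj itself lay between -0.137 and 0.18 and reversed without lung control 4, lung Cenpj mutant 2, intestine control 3 or intestine Cenpj mutant 1. The 9 genes called in both lung mutants became 0, 0, 0, 1 and 0 in 5 splits of the controls and 9 in the split giving Cenpj mutants controls 2 and 4, with fewer samples in each.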

Other observations

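Genes of the Lin28 and let-7 axis, a list chosen after the results were seen, were called lower in Ift88 mutants for 3 of 14 members in lung and 4 of 14 in intestine, without a test of the set. Plagl1 had positive values that were not called (0.17 in lung and 0.80 in intestine). In lung Igf2bp1 (-0.76), Lin28b (-1.23) and Hmga2 (-1.15) passed the limma test over all genes, and in intestine Igf2bp1 (-0.73), Lin28b (-1.50), Hmga2 (-0.92) and Arid3a (-0.95) did.

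The 2 lists bearing most directly on centriole loss did not pass in Cenpj mutant lung. The 7 genes of mitotic surveillance averaged -0.0154 (adjusted p = 0.973), and the 32 genes of centrioles and centrosomes averaged -0.0762 (adjusted p = 0.11).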
